A study of Mus musculus with 4 samples.

How the data were processed

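The deposited matrices held UMI counts of 32589 genes per cell barcode, 1 matrix for each of the 4 libraries, and were read as integers. Per the series' design text, reads were processed with CeleScope 1.9.0, Cutadapt 1.17, STAR 2.6.1b against GRCm38 with Ensembl 92 annotation, and featureCounts 2.0.1. Per the labels, cells were selected with CD45 microbeads, the chips were Singleron GEXSCOPE, and the instrument was a NovaSeq 6000. Gene places were taken from GENCODE M21, in which 67 of the gene identifiers were absent, and 52 entries shared a symbol with another. Mx1 had no entry. The molecule label reads polyA RNA for control treated0 and total RNA for the others. No file annotated cell types, so classes were rebuilt here.

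Barcodes with under 200 genes (33, 26, 10 and 13 in the order control treated0, BAP1-inactivated treated0, control treated1, BAP1-inactivated treated1) or over 20% mitochondrial UMIs (108, 250, 203 and 362) were left out. Doublets were scored per library against simulated doublets, and cells with a score over 0.2 were removed: 559, 544, 653 and 654, which is 2410 of 105031 cells. The score marked 2.38%, 2.13%, 2.26% and 2.34% of cells and found only 20.3%, 18.6%, 27.2% and 33.7% of the simulated doublets, so doublets that it misses remain in the classes. Free RNA was not subtracted before testing. Its level shows in foreign genes: C1qb stood at 970, 703, 804 and 579 CPM in neutrophil-like cells, and Pmel at 368, 749, 1643 and 1611 CPM.

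Counts were scaled to the library total and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0 with 5 starts gave 30 clusters, or 47 at resolution 2.0. Clusters led by lymphocyte or neutrophil markers were clustered again, into 20 groups. Classes were named from 19 marker sets fixed before the data were examined. The second level of clustering, the thresholds for naming and the doublet score of 0.2 were chosen after seeing the data. Clustering was run in 4 ways and the naming rule was adjusted with class shares in view, before any gene was tested.

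UMIs were summed per library and class where every library held at least 30 cells. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by genotype, quasi-likelihood F test, title number and genotype as additive factors), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The design, the tests, the alternatives planned, the marker sets and 23 gene lists were fixed before the data were examined. The 35 combinations of list, class and comparison described, from 18 lists, were chosen after their values were seen. Percentiles of list medians come from 10000 random lists matched on expression in 10 bins. Intervals of list medians run across the genes of a list, which are not independent, and hold no spread between libraries. The genes named were the 8 largest positive and negative past the threshold, with the same sign in both within-pair ratios and a mean of at least 20 CPM; where fewer passed, up to 8 at 50 CPM are given as values. Immunoglobulin and receptor segments, haemoglobin, mitochondrial and ribosomal genes, gene models and markers of other classes were left out of naming. Spp1 and Bap1 were always named.

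In a self-test on counts simulated at the common dispersion of each class, changes of 1 and 2 on the log2 scale were recovered for 14 and 77 of 100 genes in neutrophil-like cells, 67 and 98 in monocyte/macrophage-like cells, 68 and 99 in T-like cells, 12 and 60 in NK-like cells, and 82 and 98 in melanocytic-like cells. In that order, 2, 6, 6, 0 and 11 unchanged genes were called. The simulation held no difference between the pairs and no spread of dispersion between genes, so recovery in the real libraries may be lower.

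Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, no low-count filter, no second factor, doublets kept, a mitochondrial maximum of 10%, at least 500 genes per cell, immune cells as denominator, resolution 2.0, a prior count of 0.5 and leaving out each library. Neutrophil-like cells without a C1q UMI and melanocytic-like clusters of high UMI count were added after seeing the data. Other tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.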

Results

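Dissociated mouse tumours were enriched for cells bearing CD45, the surface marker of leukocytes, with magnetic beads, and the cells were profiled by single-cell RNA sequencing on microwell chips with unique molecular identifiers (UMIs). The 4 libraries combine 2 genotype labels, control and BAP1-inactivated, with a number, 0 or 1, that closes the library titles. Each of the 4 groups therefore holds 1 library, and each genotype 2. All 4 libraries carry the same treatment label, PD-1, so the labels do not say what separates treated0 from treated1, and the number serves here only to name a pair of libraries. The labels do not name the tumour type or the way BAP1 was inactivated. Titles of the BAP1-inactivated libraries begin with sh, a prefix common for short hairpin RNAs, which lower their target transcript. The series title concerns SPP1-positive neutrophils and checkpoint blockade in tumours with inactive BAP1, which made Spp1 in neutrophils and Bap1 itself the first genes to read. Values are given in the order control treated0, BAP1-inactivated treated0, control treated1, BAP1-inactivated treated1 unless stated otherwise.

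The libraries held 23522, 25587, 28961 and 27954 cell barcodes with 145433256, 150560941, 137149994 and 145623619 UMIs. The median barcode carried 3912, 3437, 3041 and 2937.5 UMIs, and no barcode carried fewer than 750. After removal of barcodes with few genes, of barcodes rich in mitochondrial transcripts and of predicted doublets, 22823, 24769, 28099 and 26930 cells remained. With 1 library per group, intervals around a single library cover counting error only (exact Poisson for UMI counts, exact Clopper-Pearson for shares, 95%), and p-values across the 4 libraries measure only the spread that an additive model of genotype and title number leaves between them, with 1 residual degree of freedom.

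Bap1, which encodes a nuclear deubiquitinase (chromosome 14, 31251450 to 31259944 on the plus strand of GRCm38), showed no loss in the libraries labelled BAP1-inactivated that passed the test. In melanocytic-like cells, the class with melanocyte lineage markers, it stood at 29.3 CPM (UMIs of the gene scaled to the total of the class) (interval 27.01 to 31.8), 26.1 (24.6 to 27.7), 31.3 (29.7 to 33.0) and 30.8 (29.5 to 32.1). Over all cells the values were 22.2, 24.4, 24.8 and 26.3. The fitted genotype change in melanocytic-like cells was -0.09 on the log2 scale (SE 0.09; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.595). Of the 10 measured genes of the BAP1 deubiquitinase complex, 0 passed the edgeR test, 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 in DESeq2. The largest value in that list was 0.41 for Mbd6, and the list median was 0.10. The transcript thus does not tell the genotypes apart in these libraries, and they are named by their labels throughout.

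**Figure D1:**
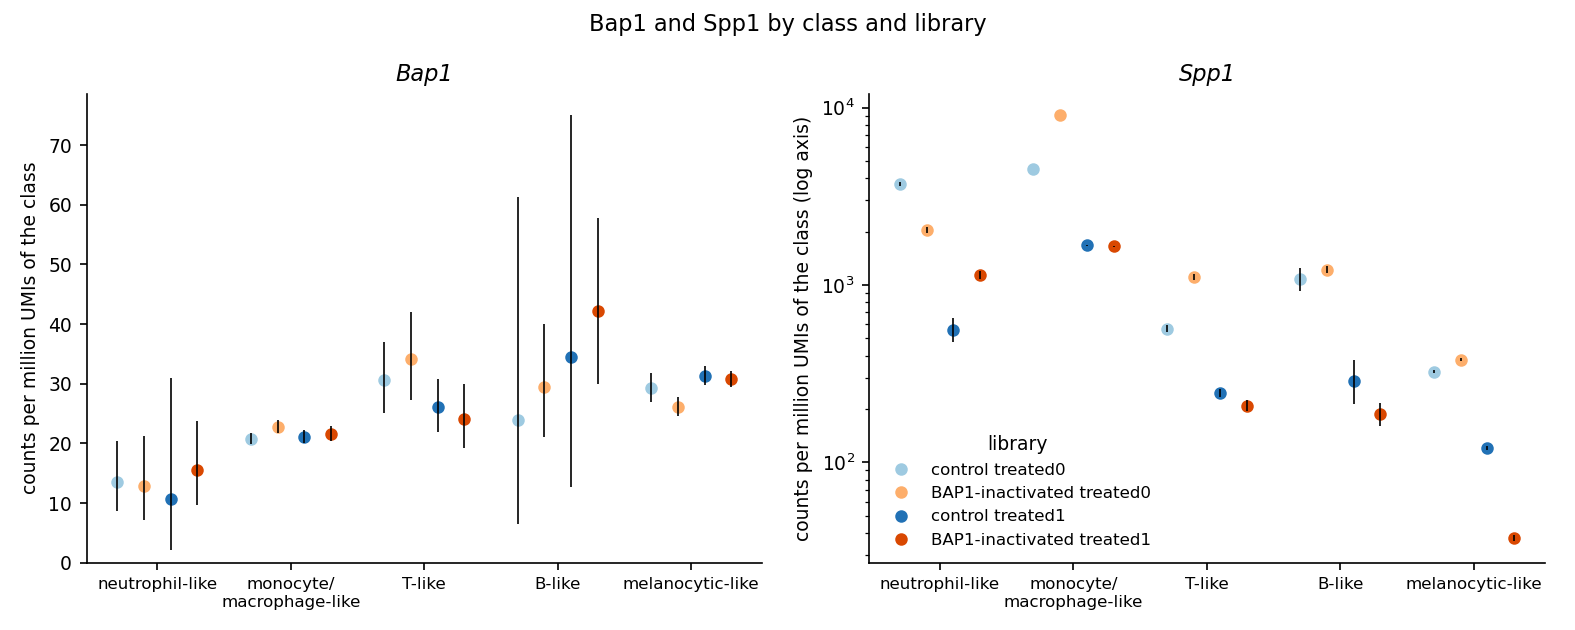
Bap1 (left, linear axis) and Spp1 (right, log axis) in CPM of each cell class; a point is 1 library and error bars are exact 95% Poisson intervals, which cover counting error only. Bap1 lies between 26.1 and 31.3 in melanocytic-like cells of the 4 libraries, and Spp1 in neutrophil-like cells falls from 3733 to 560 between the control libraries and from 2044 to 1142 between those labelled BAP1-inactivated.

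Monocyte/macrophage-like cells were the largest class in every library, and melanocytic-like and T-like cells came next among the named classes. The first had 58.9%, 49.2%, 49.6% and 47.8% of the cells of a library. Melanocytic-like cells, with Mlana, Pmel, Tyr and Dct, took 8.02%, 15.5%, 28.1% and 27.5%, although beads for CD45 were used; the labels list cancer cells beside immune cells. T-like cells had 4.96%, 4.31%, 8.16% and 6.99%, and NK-like cells 0.925%, 0.686%, 0.740% and 0.772%. The bead selection, the UMI minimum of the barcodes and cell recovery can all set such shares.

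B-like cells were the class that differed most alike between the genotype labels. They formed 0.561% (0.468 to 0.666) and 3.61% (3.38 to 3.85) of the treated0 pair and 0.459% (0.383 to 0.545) and 2.97% (2.77 to 3.18) of the treated1 pair. The log2 odds of BAP1-inactivated over control were 2.73 in both pairs, a share ratio of 6.44 and 6.46. Erythroid-like log2 odds were 0.73 (0.24 to 1.21) and 0.80 (-1.27 to 2.86), and haemoglobin over all cells stood at 970, 1903, 120 and 149 CPM. Dendritic-like cells had lower shares under the BAP1-inactivated label in both pairs, at 4.14% and 1.83%, then 3.89% and 2.83%. T-like log2 odds were -0.21 (-0.34 to -0.09) and -0.24 (-0.33 to -0.15), and the first became 0.04 with immune cells alone as the denominator.

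Neutrophil-like cells moved in opposite directions in the pairs. Their share was 4.87% (4.59 to 5.16) in control treated0 and 2.93% (2.72 to 3.14) in BAP1-inactivated treated0, but 0.754% (0.657 to 0.863) in control treated1 and 4.24% (4.01 to 4.49) in BAP1-inactivated treated1. The log2 odds were -0.76 (-0.90 to -0.63) and 2.54 (2.33 to 2.76). The class joined a cluster led by Cstdc4, G0s2 and S100a9, with 74.5%, 51.3%, 40.6% and 56.2% of its cells, and one led by Retnlg, S100a9 and Ngp with the rest. Fibroblast-like cells also moved both ways, at 0.302%, 0.650%, 2.41% and 0.405%. Clusters that met no class took 16.4%, 19.5%, 5.47% and 5.86% of the libraries. The largest of these over the 4 libraries together, of low UMI count and led by Cmss1 and haemoglobin genes, took 10.96%, 11.4%, 1.14% and 0.835%, and a cluster with neutrophil and macrophage markers together took 1.09%, 0.787%, 0.235% and 0.572%.

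**Figure D2:**
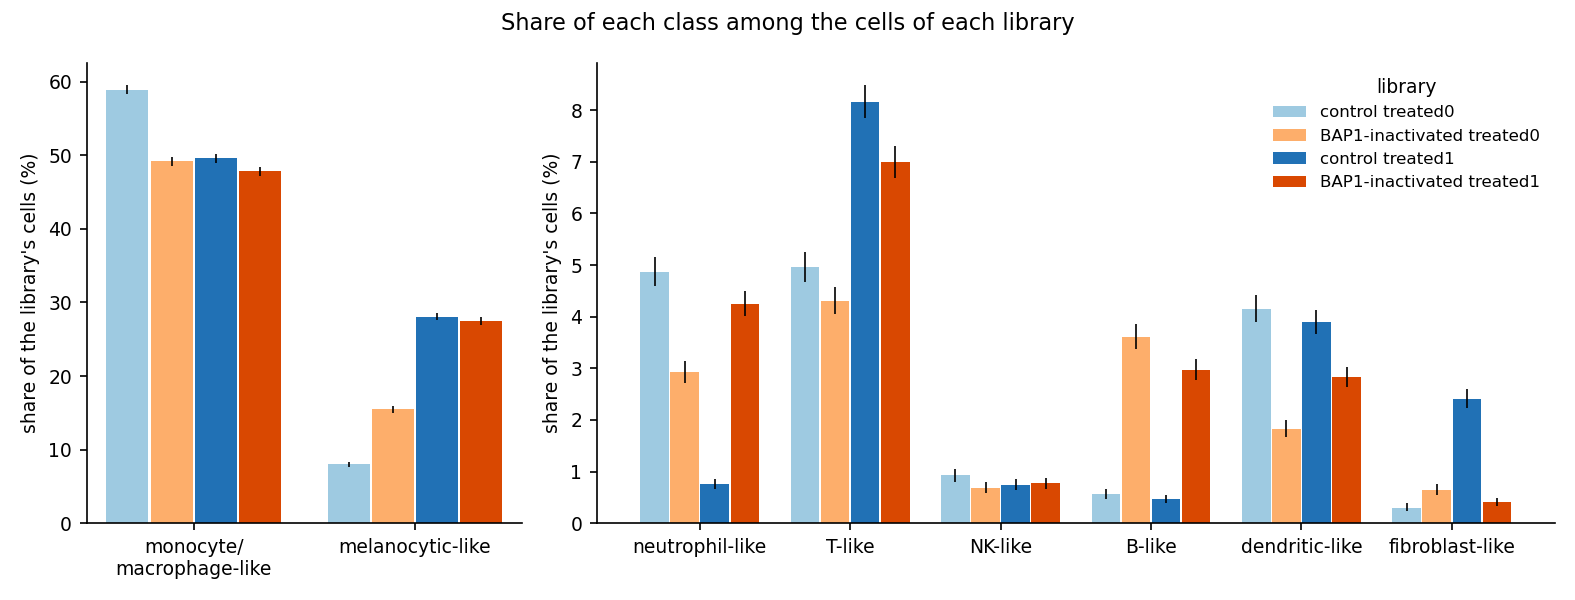
Share of each named class among the cells of each library (percent); bars are single libraries and error bars are exact 95% Clopper-Pearson intervals, which cover counting error only. B-like cells are higher in both libraries labelled BAP1-inactivated (3.61% and 2.97%) than in the controls (0.561% and 0.459%), while neutrophil-like cells run from 0.754% in control treated1 to 4.87% in control treated0.

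Spp1 encodes osteopontin, a secreted phosphoprotein (chromosome 5, 104435118 to 104441050 on the plus strand), and whether neutrophils carry more of it when BAP1 is inactive is the question the series title raises. It followed the title number more than the genotype label. In neutrophil-like cells it reached 3733 CPM (3641 to 3826), 2044 (1963 to 2127), 560 (476 to 654) and 1142 (1086 to 1201). The genotype ratio of these values was -0.87 on the log2 scale in the treated0 pair and 1.03 in the treated1 pair. With the scaling factors and prior count of edgeR, which later pair ratios of genes use, it was -1.05 and 1.11, and the fitted change was 0.01 (SE 0.46, adjusted p = 1.00, edgeR). With 1 library left out no spread remains under both factors, so such fits here and below use the tested factor alone; the value was then 1.65 without control treated0, -1.13 without BAP1-inactivated treated0, -1.44 without control treated1 and -0.21 without BAP1-inactivated treated1. The change from treated0 to treated1 was -1.98 (SE 0.48, adjusted p = 0.0655), lower in both genotypes.

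The share of neutrophil-like cells with at least 1 Spp1 UMI was 66.0% (63.1 to 68.8), 73.7% (70.3 to 76.8), 21.7% (16.3 to 27.9) and 23.1% (20.7 to 25.7), at median depths of 1266, 1272, 1099 and 1028 UMIs. T-like cells, which serve as the background from free RNA, showed 62.5%, 70.9%, 24.7% and 17.3% at 1898, 1589, 1711.5 and 1277 UMIs. After thinning every cell to 500 UMIs, with 0 cells left out, the shares were 43.7%, 46.1%, 12.7% and 15.5% in neutrophil-like cells and 25.7%, 39.3%, 9.72% and 7.81% in T-like cells. The intervals of the thinned neutrophil-like shares overlapped within each pair (40.7 to 46.6 and 42.4 to 49.8, then 8.56 to 18.0 and 13.4 to 17.7). Thinned neutrophil-like cells held 3.68, 1.57, 1.86 and 5.01 times the Spp1 UMIs per cell of the highest lymphocyte class of the same library.

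Macrophages and fibroblasts carried more Spp1 than neutrophils in every library. Monocyte/macrophage-like cells reached 4501, 9097, 1673 and 1656 CPM, and fibroblast-like cells 6895, 8613, 7595 and 6339 CPM. The largest cluster of the macrophage class was led by Cxcl3 and Il1b in control treated0 (25.8% of the class), by Mmp12 and Spp1 in BAP1-inactivated treated0 (41.2%), and by Vcam1 and Fcrls in both treated1 libraries (28.3% and 17.1%). Spp1 fell with the title number in T-like cells, by 1.83 (SE 0.21, adjusted p = 0.00035), and in NK-like cells (-1.17; SE 0.22, adjusted p = 0.0222); both hold far less Spp1 than macrophages. In monocyte/macrophage-like cells the title-number value was -2.07 (SE 0.31, adjusted p = 0.0658) and in melanocytic-like cells -2.35 (SE 0.41, adjusted p = 0.0831). The genotype values were 0.50 in monocyte/macrophage-like cells (adjusted p = 0.609) and -0.72 in melanocytic-like cells (adjusted p = 0.313), all from edgeR. After thinning, melanocytic-like cells held fewer Spp1 UMIs per cell than T-like cells in every library. Their Spp1 values thus do not stand apart from free RNA.

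Melanocytic-like cells held more genes past the genotype threshold than any immune class tested. Antigen presentation was lower: of 18 measured genes, 16 fell (18 adjusted over the list alone), with a list median of -1.18 (-1.59 to -0.59). The fixed list also holds the chemokine Cxcl9. The invariant chain Cd74 fell by 1.84 (SE 0.11, adjusted p = 0.00109), the class II chains H2-Aa by 1.69 (SE 0.10) and H2-Eb1 by 1.65 (SE 0.12), and the peptide loading factor H2-DMa by 1.59 (SE 0.14). The immunoproteasome subunits Psmb8 and Psmb9 fell by 1.55 and 1.31, the peptide transporter Tap1 (-1.05), and the class I heavy chains H2-K1 by 0.55 and H2-D1 by 0.43. B2m, at -0.42 (adjusted p = 0.0751), and Nlrc5, at -0.50 (adjusted p = 0.0662), did not pass. Cd74, H2-Aa, H2-Eb1 and H2-DMa were lower in both pairs. Macrophage transcripts were also lower in these cells, with a median of -0.66 over 8 macrophage genes, and Cd74, H2-Aa and H2-Eb1 are most abundant in monocyte/macrophage-like cells.

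**Figure D3:**
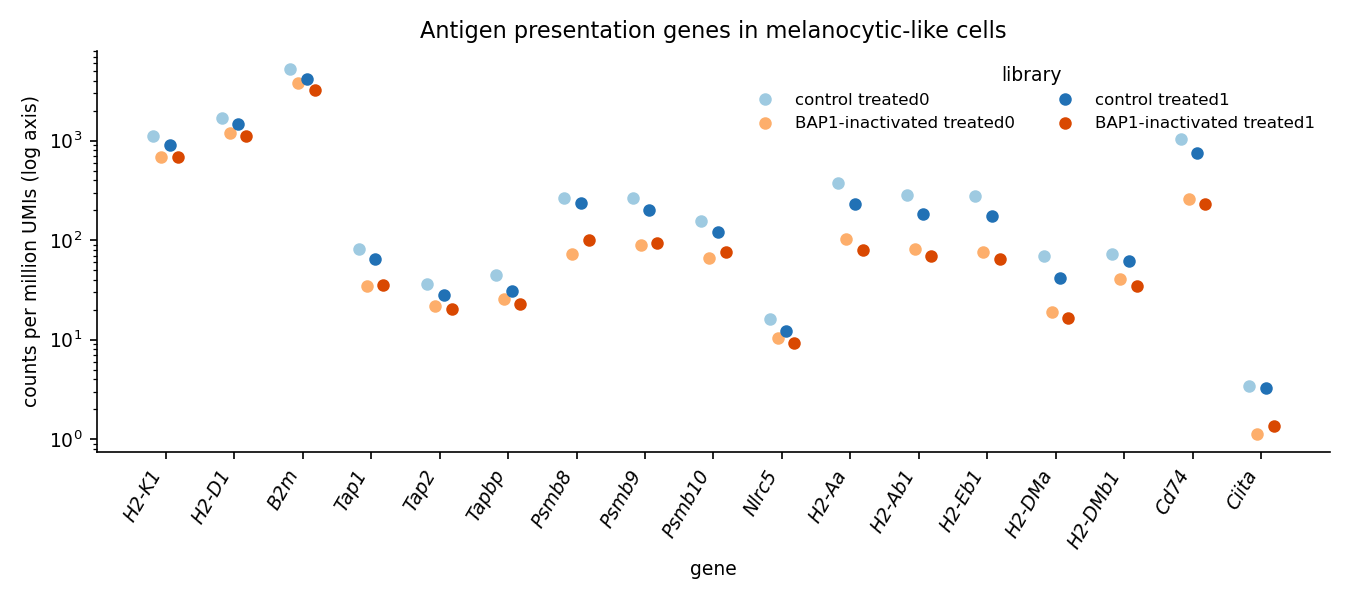
Antigen presentation genes in melanocytic-like cells, in CPM on a log axis; a point is 1 library and no error bars are drawn. For Cd74 the control libraries stand at 1038 and 754 CPM and those labelled BAP1-inactivated at 261 and 232 CPM.

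Beyond antigen presentation, the small heat shock protein Hspb1 rose by 4.05 (SE 0.13, adjusted p = 0.000206; 25.5, 356, 17.1 and 333 CPM) and the galectin Lgals7 by 3.74 (SE 0.09, adjusted p = 4.92e-05; 40.1, 529, 40.2 and 544 CPM). The microtubule minus-end protein Camsap3 rose by 2.72, the metalloproteinase inhibitor Timp3 by 2.36, the myosin light chain Myl9 by 1.97, the proton pump subunit Atp6v0d2 by 1.87 and fibronectin (Fn1) by 1.78. The peptide hormone gene Cck fell by 4.78 (SE 0.28, adjusted p = 0.00109; 207, 4.58, 244 and 12.9 CPM), and the glutamate receptor Grm3 by 1.82 (SE 0.08, adjusted p = 0.000525). The heparanase gene Hpse fell by 2.02, and the interferon-induced GTPase genes Iigp1 by 2.14 and Tgtp2 by 1.80 (-3.04 to -1.39 and -2.62 to -1.12 with 1 library left out). Hspb1 lies on chromosome 5 at 135887919 to 135889563, Lgals7 on chromosome 7 at 28863853 to 28866284, and Cck on chromosome 9 at 121489824 to 121495694.

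Other fixed lists moved less in melanocytic-like cells. Of 19 interferon response genes 3 fell (8 adjusted over the list alone), among them Cxcl10 by 0.99 (-1.67 to -0.36 with 1 library left out), with a list median of -0.49. Of 15 dissociation and immediate early genes 3 rose (7 over the list alone), including Egr1 by 0.76 and Jund by 0.57, with a median of 0.48; such genes respond to tissue handling. Among 16 mesenchymal and matrix genes 4 rose and 1 fell (4 and 1 adjusted over the list alone): Fn1, Sparc by 1.00 and Vim by 0.67 were among the former, and Tgfbi fell by 1.09. Of 18 cell cycle genes 2 fell, Tk1 by 0.53 and Tyms by 0.47; adjusted over the list alone 7 fell and 1 rose, and the list median was -0.10.

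In all, 1277 of 14931 genes passed in melanocytic-like cells, 658 higher and 619 lower, and DESeq2 called 933. The clusters behind the class differed: one of low UMI count and with cell cycle genes held 29.8%, 19.5%, 47.1% and 26.1% of it, and one of high UMI count led by Lgals7 and Nppb held 22.7%, 40.4%, 14.3% and 37.2%. Values of genes that mark these clusters thus do not separate the mix of the class from changes within its cells. Of the genes that fell, 205 were at least 5 times as abundant in another tested class, 176 of them in monocyte/macrophage-like cells. The count was 487 without control treated0, 319 without BAP1-inactivated treated0, 585 without control treated1 and 76 without BAP1-inactivated treated1.

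In T-like cells few genes of the naive, effector and checkpoint lists passed by genotype. All 12 measured naive and stem-like genes had positive values, with a median of 0.80 (0.71 to 0.85 across genes, not libraries). Over all genes 1 rose, the costimulatory receptor Slamf6 by 0.85 (SE 0.16, adjusted p = 0.0321, edgeR), and 12 did when adjusted over the list alone. The exit receptor S1pr1 stood at 1.24 (0.02 in the treated0 pair and 2.25 in the treated1 pair), the transcription factor Lef1 at 1.00 and Satb1 at 0.82. Of 15 cytotoxic effector genes 1 fell (3 over the list alone), granzyme F (Gzmf) by 1.11, while perforin (Prf1) stood at -0.72, Gzmc at -0.73 (-1.94 and 0.60 in the pairs) and Klrk1 at -0.59. All 13 checkpoint and exhaustion genes had negative values, and 0 passed the edgeR test (4 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 in DESeq2), with Tnfrsf9 at -0.55, Pdcd1 at -0.54, Havcr2 at -0.52 and Cd160 at -0.49. The largest T-like cluster was led by Nkg7, Cxcr6 and Cd8a in 3 libraries (27.1%, 29.4% and 30.4% of the class) and by Gimap3 and Trbc1 in BAP1-inactivated treated1 (31.1%). The naive genes also lead a T-like cluster of their own (Lef1, Tcf7 and Satb1) whose weight in the class differed between libraries, so their values do not separate the mix of the class from changes within its cells.

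Across T-like cells 49 of 11266 genes passed by genotype, 31 higher and 18 lower. The higher genes named by the rule, Lgals7 (1.82), Cpe (1.80), Mgarp (1.38), Pax3 (1.23), Ccn1 (1.18), Tm4sf1 (1.13), Pla2g2e (1.12) and Sparc (1.11), were all most abundant in melanocytic-like cells. The lower genes included the chemokine Cxcl9 (-1.08), the adhesion molecule Vcam1 (-1.09), the serpin Serpina3f (-1.25), the glycine decarboxylase Gldc (-1.10), Tinagl1 (-1.60), Gsta4 (-1.21) and Sv2c (-1.06). Of the 31 higher genes, 16 were at least 5 times as abundant in another class, 13 in melanocytic-like cells. Of the 18 lower genes, 6 were, with 3 in melanocytic-like, 2 in monocyte/macrophage-like and 1 in NK-like cells. DESeq2 called 5 genes, and the count was 0 without control treated0, 5 without BAP1-inactivated treated0, 0 without control treated1 and 8 without BAP1-inactivated treated1. Without control treated1 the value of Tinagl1 was 0.01 and that of Gsta4 -0.03, and without control treated0 that of Gzmf was 0.15.

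In NK-like cells interferon response genes had lower values under the BAP1-inactivated label, past the threshold only when adjusted over the list alone. That adjustment leaves out that this list, class and comparison were chosen after their values were seen. Of 17 measured members 0 passed over all genes and 9 fell adjusted over the list alone (11 at an unadjusted p under 0.05, 0 in DESeq2), with a median of -0.86 (-1.12 to -0.40). Ifit3b stood at -2.06, Ifit1 at -1.56, Ifit3 at -1.35 and Ifit2 at -1.22, and the viral RNA sensor Ifih1 at -1.58. Vcam1 (-1.98), Acod1 (-1.54), Plbd1 (-1.51), Ccl8 (-1.44), Abhd12 (-1.40) and Mgarp (1.62) completed the genes with the largest values. Of these, Vcam1 leads a cluster of the macrophage class and Ccl8 is on the list of resident-like macrophage genes. Free macrophage RNA was not tested as a source of the lower values. Of 11 cytotoxic effector genes 0 passed (0 over the list alone, 2 unadjusted, 0 in DESeq2), with Gzmc at 0.94, Gzmb at 0.92, Prf1 at 0.45 and Gzma at 0.38 and a median of 0.23. Of 5461 genes edgeR called 0 by genotype, with 362 at an unadjusted p under 0.05 and 0 in DESeq2. Leaving out control treated0, BAP1-inactivated treated0, control treated1 or BAP1-inactivated treated1 gave 12, 1, 34 and 1.

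In monocyte/macrophage-like cells no antigen presentation gene passed by genotype over all genes. The class sits in different clusters by library, as given for Spp1, so the values of this and the next paragraph do not separate its mix from changes within its cells. All 18 antigen presentation genes had negative values, with a median of -0.38 (-0.75 to -0.20); 0 passed over all genes and 7 fell adjusted over the list alone (9 unadjusted, 5 in DESeq2). H2-Eb1 and Cd74 stood at -0.88, H2-Ab1 at -0.75 and Cxcl9, a chemokine that the list includes, at -0.81. Among 11 inflammatory macrophage genes 0 passed (1 fell over the list alone, 4 unadjusted, 2 in DESeq2), with the nitric oxide synthase Nos2 at -1.05, Cd86 at -0.44, Ccl5 at -0.42 and a median of -0.40. Among 13 resident-like genes 0 passed (2 rose over the list alone, 6 unadjusted, 4 in DESeq2); the folate receptor Folr2 stood at 1.35 (SE 0.11, adjusted p = 0.069), Pf4 at 0.79, which was -0.31 without BAP1-inactivated treated0, Ccl8 at -0.66 and Selenop at 0.59, with a median of 0.14. The 15 lipid-handling genes, with Apoe at 0.96, Arg1 at 0.72, Trem2 at 0.62 and Ctsl at 0.61, had a median of 0.25 and 0 past the test (0 over the list alone, 4 unadjusted, 1 in DESeq2).

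Of 15601 genes in monocyte/macrophage-like cells 6 passed by genotype, 4 higher and 2 lower, and DESeq2 called 170. None met the naming rule; chosen after their values were seen, they include the scavenger receptor family member Cd5l (1.94), Bmp2 (2.18, and -0.32 without BAP1-inactivated treated1), and Lgals7 (3.87) and Cck (-3.67), which are abundant in melanocytic-like cells. Values without a call were Fcrls 2.06, Slfn4 1.60, Pltp 1.505, Cx3cr1 1.08, Serpina3g -1.16, Clec4b1 -1.14 and Slamf8 -1.07. The count was 0 without control treated0, 0 without BAP1-inactivated treated0, 0 without control treated1 and 1 without BAP1-inactivated treated1.

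In neutrophil-like cells 1 granule gene of immature neutrophils passed by genotype. Lactoferrin (Ltf) rose by 2.56 (SE 0.48, adjusted p = 0.0215; 21.8, 378, 113 and 222 CPM), and cathelicidin (Camp) and neutrophilic granule protein (Ngp) stood at 2.50 and 1.72, with Ltf at 3.84 and Camp at 4.64 in the treated0 pair and at 1.04 and 0.46 in the treated1 pair. Of 5 measured genes of that list 1 rose (3 adjusted over the list alone), with a median of 1.72 (-0.14 to 2.56) and Lcn2 at -0.14. The cluster led by Retnlg, S100a9 and Ngp differed in weight between libraries, so these values do not separate the mix of the class from changes within its cells. The 14 mature neutrophil genes had a median of 0.09 and 0 past the test (0 over the list alone, 0 unadjusted, 0 in DESeq2), with Mmp9 at 0.29, Csf3r at 0.25, S100a8 at -0.28 and S100a9 at -0.24. The 22 genes of the tumour-associated state, Spp1 among them, had a median of 0.03 with 0 past the test (0 over the list alone, 0 unadjusted, 0 in DESeq2); Gpnmb stood at 0.58, Egln3 at 0.49, Tgm2 at -0.39 and Fabp5 at -0.38. Of 17 genes of the antigen presentation list 0 passed (1 fell over the list alone, 2 unadjusted, 0 in DESeq2). The chemokine Cxcl9 stood at -1.28, H2-DMa at -0.74 and H2-Eb1 at -0.62, with a median of -0.41.

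Of 8379 genes in neutrophil-like cells 10 passed by genotype, 7 higher and 3 lower. Lgals7 rose by 3.91 and the glutathione transferase Gsta4 fell by 1.88, both most abundant in melanocytic-like cells, and the chemokine Xcl1, most abundant in NK-like cells, fell by 3.24. Named after their values were seen, the haemoglobin genes Hbb-bs (3.39), Hbb-bt (4.40), Hba-a1 (3.66) and Hba-a2 (3.82) were among the higher genes, while haemoglobin summed over all cells stood at 970, 1903, 120 and 149 CPM. Without BAP1-inactivated treated0 all 4 turned, to -3.17, -3.58, -3.20 and -2.63, each past the threshold. Cpe stood at 1.61 and Ccnd1 at -1.51 without a call. DESeq2 called 4 genes, and the count was 3 without control treated0, 7 without BAP1-inactivated treated0 (6 of them lower), 3 without control treated1 and 7 without BAP1-inactivated treated1.

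The title number separated the libraries within each genotype, and over the macrophage class as a whole it went with lower platelet chemokine genes and a higher Fc receptor-like gene. Clusters led by Fcrl5 and by Mmp12, Spp1 and Ctsl, the latter with Pf4 and Npy, differed in weight between libraries, so the values below do not separate the mix of the class from changes within its cells. From treated0 to treated1 the chemokines Ppbp and Pf4 fell by 2.87 and 1.69, the immunophilin Fkbp5 by 2.32 (SE 0.13, adjusted p = 0.0138), Tsc22d3 by 1.59 and Klf9 by 1.58, the protease Ctsl (-1.96), thrombomodulin (Thbd) by 1.84 and Npy by 1.66. Fcrl5 rose by 2.71 (SE 0.33, adjusted p = 0.0491), Tmem176a by 1.57, Tmem176b by 1.49, the fractalkine receptor Cx3cr1 by 1.46, Slc13a3 by 1.35, the class II regulator Ciita by 1.30 and Pdgfb by 1.27.

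Lipid-handling macrophage genes were lower in treated1: of 15 genes 2 fell, 10 adjusted over the list alone, with a median of -1.06 (-1.62 to -0.43), Fabp5 at -1.71 and Arg1 at -1.62. Of 21 hypoxia and glycolysis genes 1 fell (8 fell and 1 rose over the list alone), Egln3 by 1.37, with Hilpda at -1.11, Ndrg1 at -1.03, Pgam1 at -0.90 and a median of -0.39. Of 19 interferon response genes 0 passed (6 rose over the list alone, 8 unadjusted, 4 in DESeq2), with Oasl1 at 1.34, Cxcl10 at 1.32, Ifit1 at 1.15 and Ifit2 at 1.01 and a median of 0.45. In all 107 genes passed, 51 higher and 56 lower, and DESeq2 called 522. The count was 302 without control treated0, 95 without BAP1-inactivated treated0, and 0 without control treated1 or without BAP1-inactivated treated1.

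In neutrophil-like cells, of 14 mature neutrophil genes 2 fell from treated0 to treated1, 3 over the list alone, the collagenase Mmp8 by 1.83 and Ly6g by 1.39, with Retnlg at -1.03, Ifitm6 at -0.98 and a median of -0.53. The clusters of the class differed in weight between libraries, so values by title number do not separate its mix from changes within its cells either. The tumour-associated state had 0 of 22 genes past the test (3 fell over the list alone, 6 unadjusted, 0 in DESeq2), with Adam8 at -1.30, Fabp5 at -1.17, Ccl3 at -0.90 and a median of -0.51. All 9 measured chemoattractant genes had negative values, 0 past the test (4 fell over the list alone, 5 unadjusted, 0 in DESeq2): Cxcl3 at -2.22, Cxcl1 at -1.37, Ccl7 at -0.91, Cxcl2 at -0.79, and a median of -0.79. Of 15 lipid-handling genes 3 fell (8 over the list alone), Mmp12 by 2.07, Arg1 by 1.99 and Cd36 by 1.64, with a median of -0.79. Apart from Spp1, free macrophage RNA was not tested as a source of the lower values in these lists. The other genes that fell most were Pf4 (-2.47), Fabp4 (-2.34), Csta2 (-2.16), Fkbp5 (-2.12), Sla (-2.07), Rdh12 (-1.85) and Mmp13 (-1.84). Car6, Cenpf, Ldhb, Tnfrsf12a, Tinagl1, Car9, Sparc and Tm4sf1 rose.

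Of 8379 genes 43 passed by title number in neutrophil-like cells, 15 higher and 28 lower; 10 of the higher ones were at least 5 times as abundant in melanocytic-like cells and 10 of the lower ones in monocyte/macrophage-like cells. DESeq2 called 12, and the count was 4 without control treated0, 0 without BAP1-inactivated treated0, 64 without control treated1 and 99 without BAP1-inactivated treated1. With DESeq2 size factors in the edgeR fit 56 genes passed.

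In T-like cells 2 granzyme genes fell from treated0 to treated1, and 4 interferon-induced and 3 regulatory genes rose. Of 15 cytotoxic effector genes 2 fell (8 over the list alone), Gzmf by 1.99 (SE 0.15, adjusted p = 9.03e-06) and Gzmc by 1.84 (-2.72 to -0.79 with 1 library left out), with Gzmb at -0.88 (-1.44 to -0.27), Klrd1 at -0.56 and a median of -0.46. A cluster led by Gzmf, Gzmc, Gzmd and Gzme that also holds T cell markers met no class, so these values leave it out; it took 0.337%, 0.0606%, 0.0996% and 0.0186% of the libraries. Of 19 interferon response genes 4 rose (6 over the list alone), the chemokine Cxcl10 by 1.42, Oasl1 by 0.86, Isg15 by 0.79 and Ifit1 by 0.71, with a median of 0.25. Cxcl10, Oasl1 and Ifit1 also had positive values in monocyte/macrophage-like cells, and free RNA from those was not tested as a source. Of 12 regulatory T cell genes 3 rose (5 rose and 1 fell over the list alone), Areg by 0.89, the lineage factor Foxp3 by 0.84 and Ikzf2 by 0.66, with Gata3 at 0.60 and a median of -0.01. Foxp3 and Areg lead a T-like cluster whose weight in the class also differed between libraries. Of 13 checkpoint genes 1 fell (5 fell and 1 rose over the list alone), Tigit by 0.64, with Havcr2 at -0.52, Ctla4 at -0.42, Entpd1 at -0.41 and a median of -0.33.

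Macrophage genes fell alongside in T-like cells: of 15 lipid-handling genes 9 fell (11 fell and 1 rose over the list alone), Mmp12 by 2.18, Arg1 (-1.90) and Ctsl (-1.84), with a median of -1.07, and Cxcl3, Thbs1 and Pf4 fell by 2.31, 2.25 and 2.07. Tinagl1 (1.85), Car9 (1.498), Gsta4 (1.497), Sparc (1.34), Tspan10 (1.31), Maged1 (1.30) and Cpm (1.29) rose. Of 11266 genes 185 passed, 92 higher and 93 lower; 63 of the lower ones were at least 5 times as abundant in monocyte/macrophage-like cells and 37 of the higher ones in melanocytic-like cells. DESeq2 called 53, and the count was 76 without control treated0, 161 without BAP1-inactivated treated0, 50 without control treated1 and 59 without BAP1-inactivated treated1.

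In the edgeR fit with both factors, Ifng, the interferon gamma gene, was higher in NK-like cells of the treated1 libraries, by 1.15 (SE 0.20, adjusted p = 0.0205). Gbp5 was higher by 2.07 (SE 0.36, adjusted p = 0.0189). No higher gene passed in DESeq2 or without the second factor, where the 1 gene called each time was lower. Rgs16 rose by 1.62, Nfkbid by 1.54, Skil by 1.51, Ptgds by 1.21, Pim1 by 1.1702 and Atf3 by 1.13. The cytokine genes Csf2 and Ccl1 fell by 2.11 and 3.24. Of 17 interferon response genes 1 rose (6 over the list alone), Cxcl10 by 1.10, with Oasl1 at 0.98 and Ifit1 at 0.82, the last -0.14 without BAP1-inactivated treated0, and a median of 0.55. As in T-like cells, free macrophage RNA was not tested as a source of Cxcl10, Oasl1 and Ifit1. Of 15 lipid-handling genes 7 fell (9 over the list alone), Cd36 by 2.05, Arg1 by 1.99, Mmp12 by 1.70 and Ctsl by 1.68, with a median of -1.09, and Pf4 (-2.41), Ccl9 (-2.02) and Ccl6 (-1.90) fell. Of 5461 genes 30 passed, 16 higher and 14 lower; 5 of the higher ones, Ptgds among them, were at least 5 times as abundant in melanocytic-like cells, and 11 of the lower ones at least 5 times as abundant in monocyte/macrophage-like cells. DESeq2 called 1, and the count was 2 without control treated0, 5 without BAP1-inactivated treated0, 1 without control treated1 and 2 without BAP1-inactivated treated1.

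In melanocytic-like cells the title number moved few genes of their own. Klf11 rose by 0.94, Maff by 0.80 and Erf by 0.74. The genes that fell were those of myeloid cells: Pf4 by 2.64, Mmp12 by 2.57, Cd36 by 2.35, Thbs1 by 2.08, Ccl9 by 2.07, Cd14 by 2.05, Ccl6 by 2.02 and Adam8 by 2.01. Of 15 lipid-handling genes 5 fell (9 over the list alone), Arg1 by 2.65 among them, with a median of -0.71. All 18 cell cycle genes had positive values, with 0 past the test (14 rose over the list alone, 14 unadjusted, 0 in DESeq2), Cenpf at 0.45, Mki67 at 0.40, Ccnb1 at 0.39, Ccnb2 at 0.36 and a median of 0.28. The cluster with cell cycle genes differed in weight between libraries, so these values do not separate the mix of the class from changes within its cells. Of 14931 genes 93 passed, 4 higher and 89 lower, and 85 of the lower ones were at least 5 times as abundant in monocyte/macrophage-like cells. The count was 0 without any 1 of the 4 libraries, and DESeq2 called 162, 22 higher and 140 lower.

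The 2 genotype contrasts, which share no library, resembled each other most in melanocytic-like cells. There 69.1% of 14931 genes had the same sign in both pairs and the log2 ratios correlated across genes with Pearson's r 0.56 and Spearman's rho 0.50. In monocyte/macrophage-like cells 59.2% had the same sign (r 0.22, rho 0.22), in T-like cells 60.7% (r 0.18, rho 0.24), in NK-like cells 52.0% (r 0.06, rho 0.06) and in neutrophil-like cells 47.3% (r -0.02, rho -0.06). These correlations run across genes, which are not independent replicates, and carry no p-value.

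**Figure D4:**
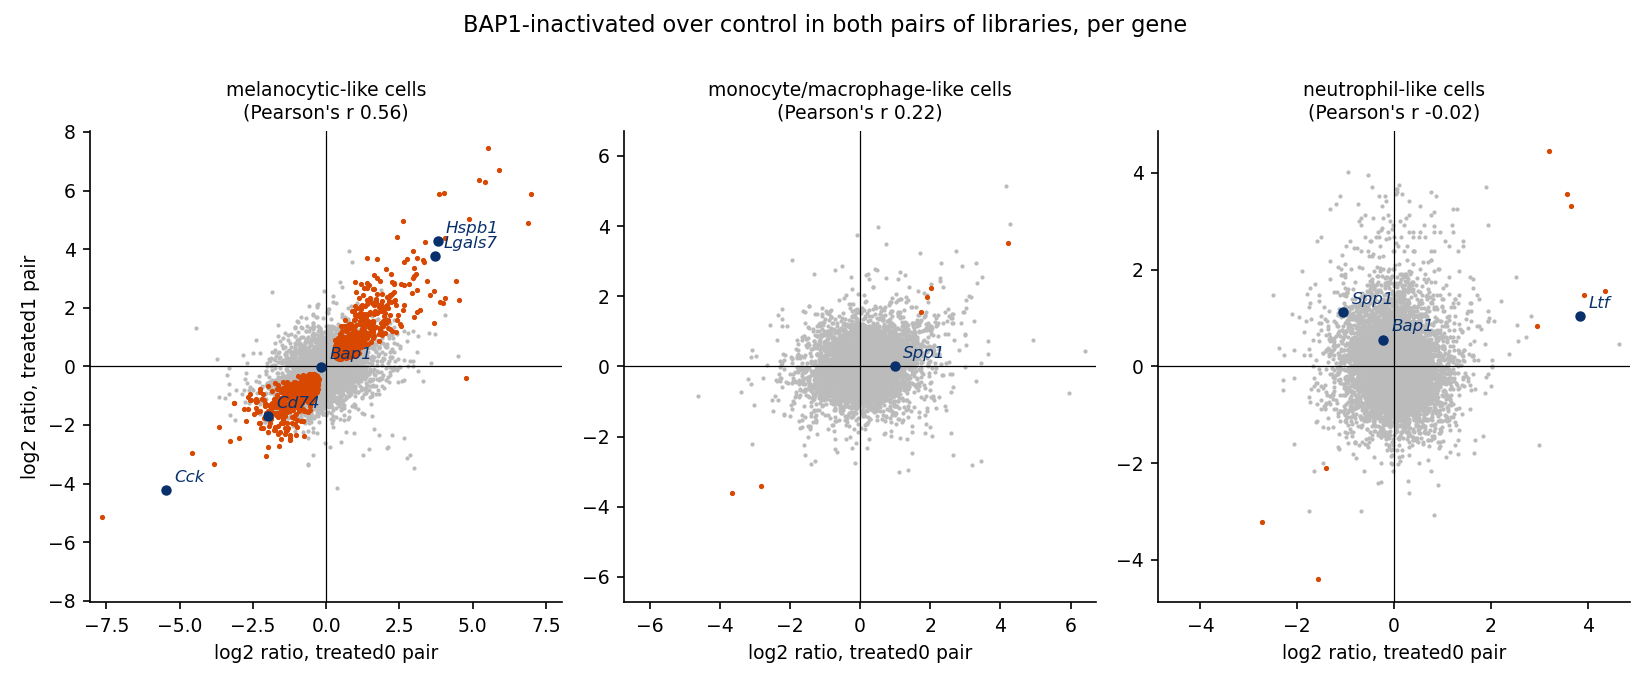
Log2 ratio of BAP1-inactivated over control for each gene in the treated0 pair (horizontal) and the treated1 pair (vertical), in melanocytic-like, monocyte/macrophage-like and neutrophil-like cells; a point is a gene, orange points passed the edgeR test by genotype, and named genes are in blue. The clouds align in melanocytic-like cells (r 0.56) and not in neutrophil-like cells (r -0.02), whose sums hold far fewer UMIs. In neutrophil-like cells Spp1 lies at -1.05 and 1.11 after edgeR scaling.

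Where the pairs differed, no test was possible, since 4 libraries leave nothing to estimate the spread from. The largest differences of the log2 genotype ratios (treated1 pair minus treated0 pair) in neutrophil-like cells were those of the activin gene Inhba (4.50), the interferon-induced Gbp2 (3.29), Csta2 (3.21), Il1a (2.99) and Blcap (2.52) on one side, and Camp (-4.18), Ltf (-2.80), Ccl5 (-2.61), Tinagl1 (-2.12) and Mgll (-2.03) on the other. Spp1 differed by 2.16 there. In monocyte/macrophage-like cells Ifitm1 (3.26), Inhba (2.57), Cxcl3 (2.47), Slpi (2.29) and Slfn4 (2.28) led, against Syngr1 (-1.83), Gpnmb (-1.77), Atp6v0d2 (-1.74), Fcrls (-1.63) and Fabp5 (-1.41). In T-like cells Gzmc (2.54), S1pr1 (2.23), Serpinb6b (1.86), Serpine2 (1.67) and Lef1 (1.51) stood against Cryab (-1.82), Ptgds (-1.57), S100a1 (-1.56), Mmp12 (-1.48) and Syt4 (-1.39). In NK-like cells the extremes were Cxcl3 (4.33) and Ifitm1 (4.25) against Ccnb2 (-2.59) and Phf6 (-2.27), and in melanocytic-like cells Gxylt2 (1.68) and Vgll3 (1.27) against Spp1 (-1.92) and Hspa1b (-1.66).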

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

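The tests of free RNA, of cells without a C1q UMI, of clusters with high UMI counts, of the recovery of CD45-negative cells and of blood in this part were chosen only after the results were seen, and that of recovery was split by pair once its values were known.

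The genotype contrast had opposite signs in the pairs for 4 class shares and for Spp1 in 4 of the 5 tested classes. This counts only those whose intervals, which cover counting error only, exclude 0 in both pairs. With 1 library per group none of these differences was tested. The log2 odds in the treated1 pair minus those in the treated0 pair were 3.31 for neutrophil-like cells (-0.76 and 2.54 in the treated0 and treated1 pairs), 2.55 for endothelial-like cells (-1.05 and 1.501), -3.71 for fibroblast-like cells (1.11 and -2.60) and -2.79 for plasmacytoid dendritic-like cells (1.00 and -1.79). Melanocytic-like (1.07 and -0.04) and NK-like shares (-0.43 and 0.06) also had opposite signs, with an interval that includes 0 in the treated1 pair. For Spp1 as a share of all UMIs of a class, the same difference of log2 ratios was 1.899 in neutrophil-like cells (-0.87 and 1.03), -1.03 in monocyte/macrophage-like cells (1.02 and -0.01), -1.21 in T-like cells (0.97 and -0.24) and -1.92 in melanocytic-like cells (0.22 and -1.70). In monocyte/macrophage-like cells the treated1 ratio was close to 0 (1673 and 1656 CPM, interval -0.027 to -0.002), so an opposite direction is not shown there. T-like cells serve above as the background from free RNA.

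Spp1 in neutrophil-like cells was lower in treated1 than in treated0. Thinned neutrophil-like cells held at least 1.57 times the Spp1 UMIs of the highest lymphocyte class in every library. This argues against free RNA as its only source if free RNA enters all classes alike, which was not tested. The shares of thinned cells with Spp1 had intervals that overlapped those of B-like cells in BAP1-inactivated treated0 (42.4 to 49.8 against 38.0 to 44.6) and in control treated1 (8.56 to 18.0 against 6.06 to 17.5), but not in the other libraries. Doublets with macrophages stay open. Without cells holding a C1q UMI, 0.558 of the mean log2 drop was left. The log2 ratio was then -1.80 (-2.21 to -1.38) between the controls and -0.20 (-0.41 to 0.009) between the BAP1-inactivated libraries, against -2.74 and -0.84 in all neutrophil-like cells. But only 191 of 1111, 171 of 725, 49 of 212 and 419 of 1143 cells remained. Free C1q RNA also marks cells as doublets do, so these values do not bear on doublets. What the title number stands for is not known, so no biological explanation was tested.

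The lower antigen presentation genes in melanocytic-like cells labelled BAP1-inactivated met 3 tests of technical explanations. More cells of low UMI count in the controls were not needed for the fall. Within the clusters of high UMI count the list median was 1.01 times that in all clusters, and 16 of 18 genes passed. But these clusters held most UMIs of the class in each library, so leaving out the others could move the ratio little. They held 17984972 of 19974029, 38333601 of 41462616, 36911628 of 45948088 and 64384826 of 68892819 UMIs. Among them the cluster led by Lgals7 and Nppb differed in weight between libraries, which was not tested as a source. Less free macrophage RNA is argued against for the class I and proteasome genes, of whose fall 0.924 was left after subtraction. By the criterion set first it was not, since the macrophage genes had a median of -0.66 and the class I and proteasome genes -0.60. The subtraction was added after that value was seen. For the class II genes the cause cannot be told apart from free RNA, because the estimate would supply up to 106% of their UMIs in a library. The genotype named by the label stays open for both parts and was not tested apart from them.

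The neutrophil-like share was lower in BAP1-inactivated treated0 and higher in BAP1-inactivated treated1 than in the control of the pair. The UMI minimum stays open, since at 1500 UMIs the smaller remaining size was 0.748 of the log2 odds. Unequal recovery of CD45-negative cells stays open in the treated0 pair, with 0.687 of the log2 odds left over immune cells alone, and is argued against in the treated1 pair, with 0.994 left. Blood carried in the tumours is argued against in the treated0 pair, where haemoglobin was higher by 0.97 on the log2 scale in the library with fewer neutrophil-like cells. In the treated1 pair haemoglobin went the same way as the share, but by 0.31 where the log2 odds of the share were 2.54. The test took only directions, so it does not show how much blood contributed there. A difference by genotype stays open and untested.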

How the results depend on the processing

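The fits without a low-count filter for Spp1 and Bap1, the neutrophil-like cells without a C1q UMI and the melanocytic-like clusters of high UMI count were chosen only after the results were seen; for every change below the cause was not tested, except that the denominator sets shares by construction.

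Counts of genes past the threshold are given as genotype, then title number. With DESeq2 they were 4 and 12 in neutrophil-like, 170 and 522 in monocyte/macrophage-like, and 5 and 53 in T-like cells, and by title number 1 in NK-like and 162 in melanocytic-like cells. DESeq2 size factors in edgeR gave 3 and 25 in monocyte/macrophage-like and 7 and 94 in T-like cells. Without a low-count filter the counts were 25 and 115 in neutrophil-like, 11 and 199 in monocyte/macrophage-like, 274 and 396 in T-like, 37 and 87 in NK-like, and 2403 and 633 in melanocytic-like cells. Without the second factor they were 0 and 11 in neutrophil-like, 0 and 0 in monocyte/macrophage-like, 0 and 20 in T-like and 407 and 0 in melanocytic-like cells, and 1 by title number in NK-like cells. With doublets kept, 3 and 26 genes passed in monocyte/macrophage-like cells, 17 by title number in neutrophil-like cells and 17 by genotype in T-like cells. With a mitochondrial maximum of 10% the counts were 16 and 73 in neutrophil-like, 3 and 26 in monocyte/macrophage-like, and 168 and 303 in T-like cells, and 8 by title number in NK-like cells. Neutrophil-like cells without a C1q UMI gave 3 by genotype, and melanocytic-like clusters of high UMI count 173 by title number.

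Fits that leave out a library also leave out the second factor, since no spread remains otherwise, so their ranges mix both changes. They gave, by genotype and title number, 3 to 7 and 0 to 99 genes in neutrophil-like, 0 to 1 and 0 to 302 in monocyte/macrophage-like, 0 to 8 and 50 to 161 in T-like, 1 to 34 and 1 to 5 in NK-like, and 76 to 585 and 0 to 0 in melanocytic-like cells; the lone library of an arm is assumed to vary like the others. The genotype value of Spp1 in neutrophil-like cells ranged from -1.44 to 1.65, and that of Bap1 in melanocytic-like cells from -0.23 to 0.020. The former also changed sign with DESeq2 size factors (-0.0039), without the second factor (-0.60) and without C1q-positive cells (-0.37). Of genes named among many, Tinagl1 (-2.44 to 0.0098) and Gzmf (-2.44 to 0.15) in T-like cells, Pf4 (-0.31 to 1.85) and Bmp2 (-0.32 to 4.64) in monocyte/macrophage-like cells, and Hbb-bs (-3.17 to 14.5), Hbb-bt (-3.58 to 12.5), Hba-a1 (-3.20 to 14.0) and Hba-a2 (-2.63 to 8.22) in neutrophil-like cells changed sign by genotype, and Ifit1 in NK-like cells by title number (-0.14 to 2.13), each when 1 library was left out.

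Shares follow the order control treated0, BAP1-inactivated treated0, control treated1, BAP1-inactivated treated1. Over immune cells alone they were 6.50%, 4.61%, 1.18% and 6.44% for neutrophil-like, 78.7%, 77.6%, 77.6% and 72.6% for monocyte/macrophage-like, 6.63%, 6.79%, 12.8% and 10.6% for T-like, 1.24%, 1.08%, 1.16% and 1.173% for NK-like, and 0.749%, 5.69%, 0.719% and 4.51% for B-like cells, with log2 odds of -0.52 for neutrophil-like and -0.10 for monocyte/macrophage-like cells in the treated0 pair, -0.39 for the latter in the treated1 pair, and a reversed 0.037 for T-like cells in the treated0 pair. At 500 genes per cell neutrophil-like shares were 3.74%, 2.50%, 0.621% and 3.12% (log2 odds -0.60 in the treated0 pair), and monocyte/macrophage-like shares 59.8% in control treated0 and 48.5% in BAP1-inactivated treated1. At resolution 2.0 the latter class had 54.3%, 43.9%, 47.6% and 45.0%, and T-like cells 4.30% and 3.81% in the treated0 pair; with doublets kept, monocyte/macrophage-like cells had 47.1% in BAP1-inactivated treated1.

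The share of neutrophil-like cells with Spp1 was 43.7%, 46.1%, 12.7% and 15.5% when thinned to 500 UMIs, 58.4% and 62.9% in the treated0 libraries when thinned to 1000, 43.3%, 48.4%, 10.4% and 12.5% with at least 2 Spp1 UMIs, and 69.0% and 77.0% in the treated0 libraries at 500 genes per cell. At 50 CPM the mesenchymal list median in melanocytic-like cells was 0.83, and with CPM alone the lipid-handling median by title number in neutrophil-like cells was -0.58. Among genes at 50 CPM or more, the same sign in both pairs, Pearson's r and Spearman's rho were 43.1%, -0.075 and -0.19 in neutrophil-like and 70.7%, 0.75 and 0.62 in melanocytic-like cells; the share was 67.0% in T-like cells, and rho 0.42 there and 0.25 in monocyte/macrophage-like cells. A further 67 list medians stayed the same, and 1 list had too few genes at 50 CPM for a value. Of the other named genes' genotype values 424 kept their side of the threshold, 38 passed and 88 no longer passed under alternatives that kept all libraries, and by title number 571, 32 and 200. With 1 library left out, 192 kept it, 10 passed and 130 no longer passed by genotype, and 230, 14 and 263 by title number, so more title-number values were lost than kept.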

Other observations

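The test of the glucocorticoid hypothesis in this part was chosen before its result was seen. The lineage genes below were chosen only after their values were seen.

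Of 5 lineage genes of melanocytic-like cells 1 fell and 1 rose under the BAP1-inactivated label. These were Mlana, which encodes a melanosomal antigen and fell by 0.93 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, adjusted p = 0.00701), and Mitf, the lineage's transcription factor, which rose by 0.61 (adjusted p = 0.0171). Pmel stood at 0.20, Dct at -0.13 and Tyr at -0.21.

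Fkbp5, Tsc22d3 and Klf9, which glucocorticoids induce, fell from treated0 to treated1 in monocyte/macrophage-like cells, so a weaker glucocorticoid response in the treated1 libraries may be one source of the change. The test took 8 other induced genes, whose median in that class was -0.72 (-1.10 to 0.89), below all 10000 random lists. Ddit4 fell by 1.08 and Per1 by 0.77, while Zbtb16 stood at -1.10, Mt2 at -0.85, Mt1 at -0.67, Sgk1 at -0.40, Errfi1 at -0.15 and Pdk4 at 0.89. The medians in the other classes were not that low, at -0.16 in neutrophil-like (percentile 34.5 of random lists), 0.17 in T-like (98.7, so the other way), 0.20 in NK-like (91.2) and 0.04 in melanocytic-like cells (55.4), although Fkbp5 fell by 1.22 in T-like and 2.12 in neutrophil-like cells too, and Tsc22d3 by 0.99 in T-like and 1.25 in melanocytic-like cells. Found and tested on the same libraries, this stays a hypothesis.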
